A study of Arabidopsis thaliana with 12 samples.

How the data were processed

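Total RNA of wild-type Arabidopsis thaliana, ecotype Wassilevskija, was profiled on arrays in 12 samples, 6 labelled water and 6 labelled as treated for 6 h in MS medium with 60 mM sucrose. MS (Murashige and Skoog) medium is a mineral salt mixture for plant tissue culture, so the treated samples differ from water by at least the medium and the sugar. The water labels carry no time, so time and handling may differ as well. The array type, the scanner, the label on the RNA, the plant organ and age, the length of the water treatment and the meaning of the sample numbers 1 to 6 are not given in the sources used here. Nothing in the labels says that samples of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical.

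The deposited values are linear spot intensities, 1 per probe and sample, for 3439 probes. How the authors subtracted background or scaled these intensities is not given in the sources used here. The deposited intensities carry an exact 0 in 13.6% of all values, and 2 to 8 probes per sample sit at a common ceiling whose meaning is not stated. The scale is in arbitrary units, what its 0 stands for is not stated, and the number of arrays limits the precision. Per-sample medians of deposited intensity were 0.171 to 0.188 in water and 0.309 to 0.339 in MS with sucrose.

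The rules for the scale and the fit were set before the data were examined. Because over 1% of values were 0, values were used as log2(intensity + 0.0718), where the offset is the 10th percentile of the values above 0. Because the medians of the 12 samples lay 0.76 apart on that log2 scale, more than the 0.1 allowed, the samples were quantile normalized. A fold change on this scale understates the change of dim probes, and a change is relative to the other probes of the array. Each probe was then tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, 6 against 6 samples, two-sided), with Benjamini-Hochberg adjustment over 3439 probes, no filter on level, and a threshold of 0.05 on the adjusted p. Figures were drawn with matplotlib 3.10.9.

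Probe names come from the platform annotation supplied with the series, updated through gene identifiers to the symbols of the TAIR10.1 gene table, from which no coordinates were taken. Of the probes, 692 had 1 gene, 870 had several and 1877 are unnamed here; 690 of the 692 matched the table, and they stand for 691 genes. No gene is named from a probe with several. Where a gene had more than 1 probe, the probe with the highest mean level was used.

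The genes named are the 12 largest rises and the 12 largest falls among probes of 1 gene past the threshold. To these are added, for each gene list, up to 2 risers and up to 2 fallers with the smallest p, or 1 member as a value where none passed. A fixed set of 11 nitrate, starch, sugar and stress genes was to be named whatever its values, but none of them had a probe of its own. The 24 lists written before the data were examined held 404 genes, of which 7 had such a probe, in 4 lists: photosystem and electron transport subunits, light-harvesting proteins, Calvin cycle, and sucrose cleavage and synthesis. Markers of root and seed and the reference genes had none, and a list of cytosolic ribosomal proteins matched no gene because the tables used here carry no descriptions. After the data were seen, 9 further lists were written from the genes with a probe of their own. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, separately adjusted for the planned and the added lists.

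The sample numbers were checked for pairing through the correlation, across probes, of deviations from the group means; probes are not independent replicates. Water and MS with sucrose samples of the same number correlated at 0.174 to 0.390 in the 6 pairs, and 11 of the 12 samples were closest to their own number in the other group, so the numbers pair the samples; this pairing comes from the data, not from the labels. Within a group, numbers 1 and 2, 3 and 4, and 5 and 6 also correlated, at 0.121 to 0.309 in water and 0.133 to 0.157 in MS with sucrose, against -0.447 to -0.134 for the other combinations. Deviations from a shared mean are pulled towards negative correlation, so the negative values do not show samples deviating in opposite directions. Because adjacent numbers correlated, the fit was repeated, after the data were seen, on the averages of these adjacent numbers, 3 against 3. The other alternatives were the deposited scale, median centring, cyclic loess, another offset, zeros as missing, filters on dim probes, the number as a block, other variance models, other list tests, and each sample left out.

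The fit was tested on simulated data with 200 of 3439 probes changed, in 10 runs. With independent errors, 6 against 6 samples recovered 77.5% of the changes of 1 on the log2 scale and 38.8% of those of 0.5, with 6.28% of calls false. With a correlation of 0.337 between adjacent numbers of a group, as estimated from the data, the share of false calls was 18.8%. Averaging adjacent numbers brought it to 4.29% with 42.5% of the larger changes recovered. The simulated errors were independent between the groups, whereas in the data same and adjacent numbers also correlated across the groups. The share of false calls also depends on how many probes change, so these shares need not hold for the data.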

Results

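The series measured RNA levels in wild-type Arabidopsis given MS medium with 60 mM sucrose for 6 h, or water for a time not given. Each group had 6 samples. Its labels name 1 comparison, sucrose in MS medium against water. Deposited intensities were brighter over most of the array after MS with sucrose, with a median of 0.323 ± 0.0128 (SD, n = 6) against 0.177 ± 0.00806 (SD, n = 6) in water. The 25 brightest probes held 34.5% ± 0.268 (SD, n = 6) of the signal after MS with sucrose and 45.1% ± 0.887 (SD, n = 6) in water. Differences below are log2 differences, MS with sucrose minus water, after quantile normalization, with the SE and the adjusted p of limma. Unless another setting is named, the fit takes the 12 samples as independent. The correlations of adjacent numbers argue against that, so the SE and adjusted p may be too small. Intensities are as deposited.

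**Figure D1:**
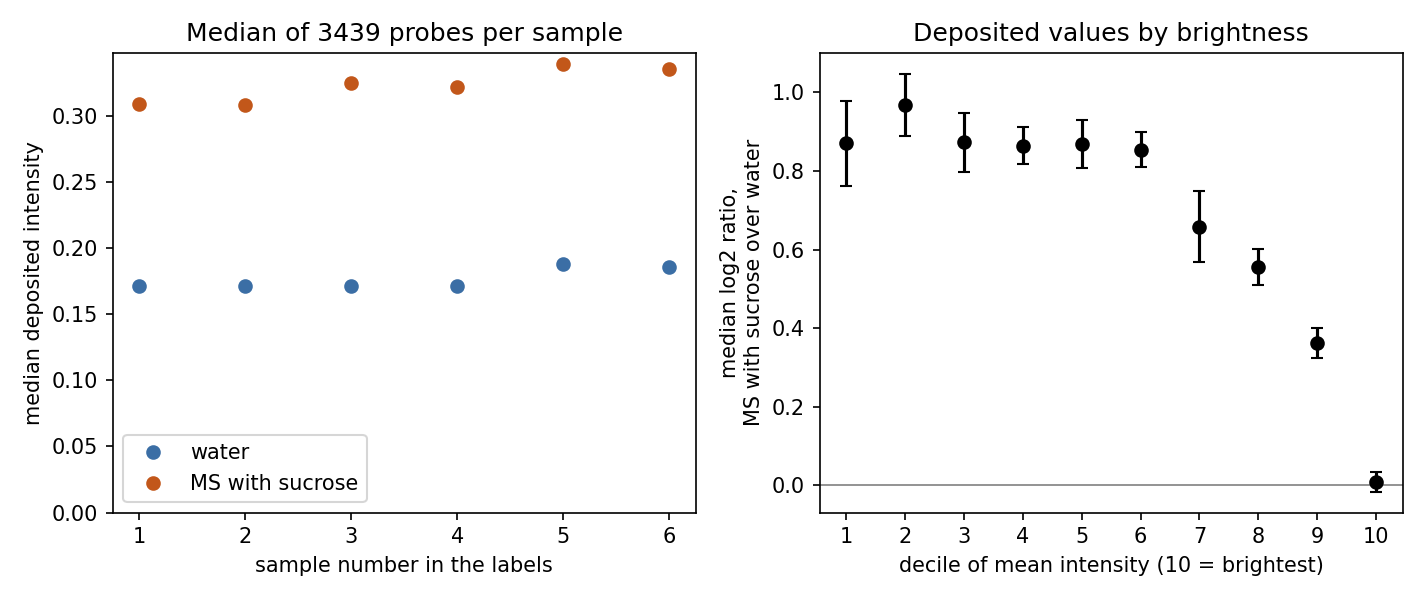
Left, median deposited intensity of each sample against its number in the labels, on a linear axis from 0; right, median log2 ratio of MS with sucrose over water by decile of mean intensity, as mean and SD over the 6 same-numbered pairs, for the 2575 probes above 0 in all samples. The ratio is 0.87 in the first and the fifth decile and 0.01 in the brightest.

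Cyanase (CYN, AT3G23490), which breaks down cyanate, had the largest fitted fall among genes with a probe of their own, and AT4G18180 the largest fitted rise. CYN dropped from an intensity of 8.83 ± 1.68 (SD, n = 6) in water to 1.29 ± 0.237 (SD, n = 6), a difference of -2.84 (SE 0.14, adjusted p = 8.15e-08 by limma). AT4G18180 went from 0.110 ± 0.0199 (SD, n = 6) to 1.24 ± 0.171 (SD, n = 6), a difference of 2.40 (SE 0.12, adjusted p = 8.15e-08 by limma). With adjacent numbers averaged, CYN and AT4G18180 each had an adjusted p of 0.00197 by limma. AT4G18180 did not lead under every setting: the rise of AT1G76450 was larger with cyclic loess and with the offset at the 25th percentile (2.12 against 2.07), and that of AGL54 with zeros missing (3.07 against 2.94). A PsbP-domain protein gene (AT1G76450) and the plastid ribosomal protein L29 gene (AT5G65220) rose too, while an aprataxin-like gene (APTX) and the chromatin remodeling gene chr31 fell. In all, 624 probes were higher and 665 lower after MS with sucrose, of which 175 and 173 differed by at least 2-fold. Quantile normalization gives the samples a common distribution, which by itself pulls this split towards even. Among the 692 probes with 1 gene, 139 were higher and 118 lower. Of these, 110 and 42 were called the same way under all 4 scalings, a split that depends on which scalings are compared. With adjacent numbers averaged, 75 and 76 were called.

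AT1G76450 rose by 2.25 (SE 0.12), from 0.451 to 2.97 in mean intensity. AT1G12800 rose by 1.86 and AT1G13990 by 1.82, from 0.583 to 2.84 and from 0.546 to 2.63 in mean intensity. AGL54 (AT5G27090), of the AGAMOUS-like MADS-box family, rose by 1.82 from an intensity of 0.0758 near the offset. AT4G37230 was listed at 0 in 5 of the 6 water samples and averaged 0.256 after MS with sucrose, so its difference of 1.80 depends on the offset. AT4G17650 rose by 1.70, AT1G06730 by 1.54, and DRT101 (AT5G18070) was 2.63-fold higher on the normalized scale, from 0.131 to 0.731 in mean intensity. A water mean under 0.143, the 25th percentile of the values above 0, was found for 4 of the 12 genes. AT5G65220 rose by 1.53, from 1.94 ± 0.263 (SD, n = 6) to 6.05 ± 1.78 (SD, n = 6). AT4G05070 was 2.82-fold higher on the normalized scale, from 0.193 to 0.892 in mean intensity, and AT1G01080 rose by 1.43. Together with AT1G06730 they had the widest errors of the 12 (SE 0.41, 0.35 and, for AT1G06730, 0.39). Of the 12 genes, 11 were above the water mean in 6 of 6 samples, and AT1G06730 in 5. Sample 3 of AT1G06730 was low in both groups, at 0.209 in water and 0.616 after MS with sucrose. Compared within same-numbered pairs, AT1G06730 and AT1G01080 were higher after MS with sucrose in each pair. All 12 passed under each of 4 scalings; with adjacent numbers averaged, 10 passed, and AT4G05070 (adjusted p = 0.114 by limma) and AT1G01080 (adjusted p = 0.109 by limma) did not. AT1G06730 missed the threshold without numbers 1 and 2 of both groups (adjusted p = 0.114 by limma) and without numbers 5 and 6 (adjusted p = 0.0889). AT1G01080 missed it without numbers 5 and 6 (adjusted p = 0.101), but passed when the averages were also paired by a replicate block. AT4G05070 missed it without numbers 5 and 6 (adjusted p = 0.0687), with array weights (adjusted p = 0.0683) and with a replicate block on the averages (adjusted p = 0.0812).

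Below CYN, AT4G31930 (-2.38), AT2G21720 (-2.29), APTX (AT5G01310, -2.27) and chr31 (AT1G05490, -2.15) fell the most. GH9B12 (AT2G44570), a member of glycosyl hydrolase family 9, fell by 1.78, and AT1G24040 fell by 1.54; both were listed at 0 in 2 of the 6 samples after MS with sucrose, and AT4G31930 in 1. AT4G25290 fell by 1.41, AT4G08940 by 1.36 and AT1G11730 by 1.34, and AT5G36470 was 2.63-fold lower. AT3G09080 was at 19.7 ± 1.96 (SD, n = 6) in water and 7.12 ± 0.873 (SD, n = 6) after MS with sucrose, a fall of 1.35. All 12 were below the water mean in 6 of 6 samples, and the groups did not overlap for any of them. Because these genes were picked for large falls in the same samples, such separation is largely built in. Of all probes, 434 lower and 353 higher ones showed no overlap. All 12 passed under each of 4 scalings and with adjacent numbers averaged, where their adjusted p by limma ran from 0.00197 to 0.0459. APTX missed the threshold when these averages were also paired by a replicate block (adjusted p = 0.0524 by limma).

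**Figure D2:**
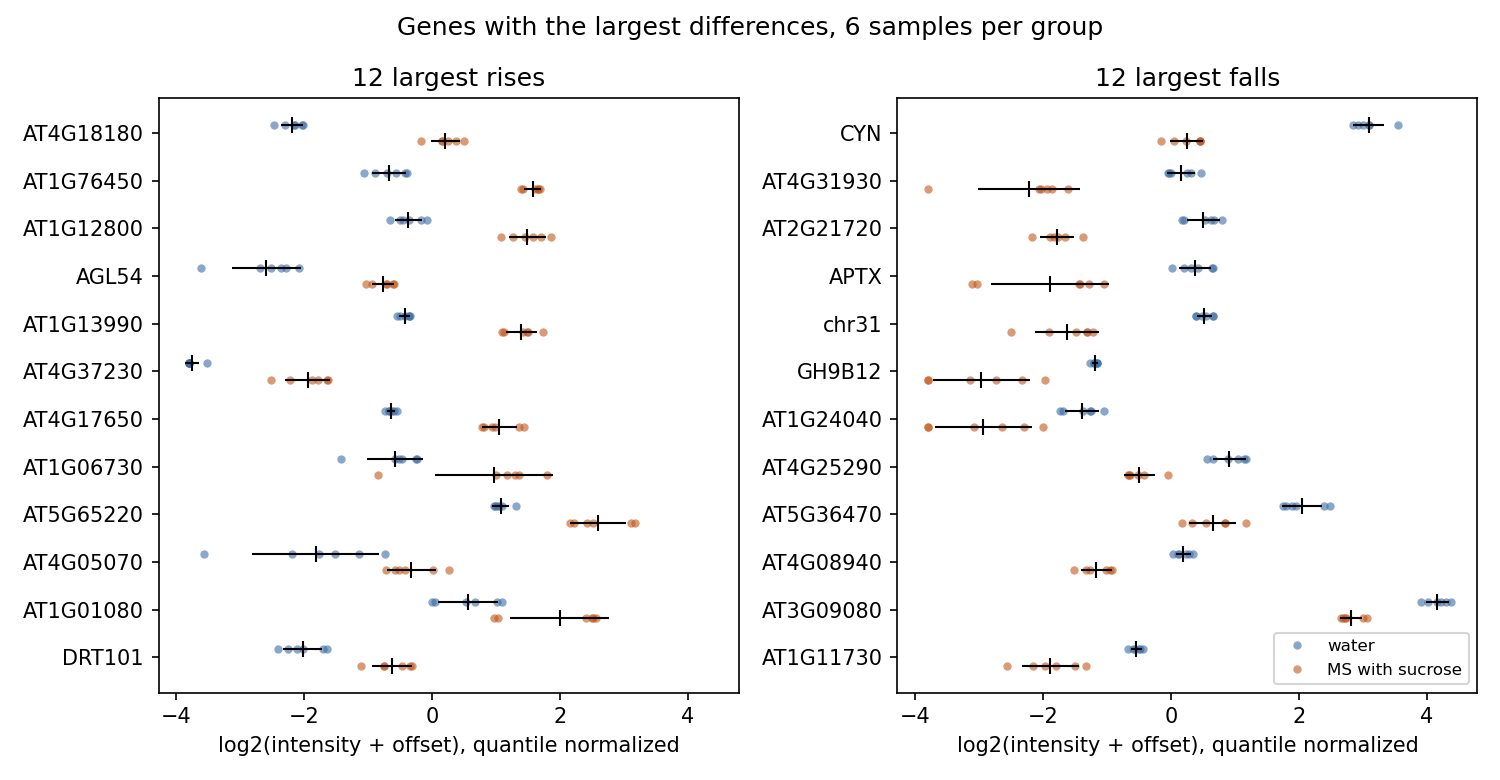
Log2(intensity + offset) after quantile normalization for the 12 largest rises (left) and the 12 largest falls (right); each point is 1 of the 6 samples of a group, the vertical tick is the group mean and the horizontal bar its SD. CYN differs by -2.84 and AT4G18180 by 2.40, and the samples of AT1G06730 and AT1G01080 overlap between the groups.

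Of the 3 photosystem and electron transport subunits, the photosystem II subunit gene PSBW (AT2G30570) was higher by 0.63 (SE 0.09, adjusted p = 0.000163 by limma), PSBY was at -0.16 and PSAN at -0.24, and the last 2 did not pass. Adjusted over the list alone, 2 of the 3 passed, in opposite directions: PSBW was higher and PSBY lower. With adjacent numbers averaged, PSBW had an adjusted p over all probes of 0.0166 by limma. PSBW took the opposite sign when each array was centred on its median, at -0.53, and was at 0.14 on the deposited scale, where the median of all probes was 0.38; under median centring that median was -0.29. Of the 3 subunits, 1 rose and 0 fell with quantile normalization or cyclic loess, 0 passed on the deposited scale, and 0 rose and 3 fell under median centring. The list was not called by camera (adjusted p = 0.903, and adjusted p = 0.905 with an estimated correlation), with a mean of 0.07 and a median of -0.16 that differ in sign. PRK (AT1G32060), the Calvin cycle phosphoribulokinase, rose by 0.80 (SE 0.10, adjusted p = 0.00011 by limma), from 1.93 to 3.64 in mean intensity. With adjacent numbers averaged, PRK had an adjusted p of 0.0194 by limma. Among the scalings, PRK missed the threshold only under median centring (0.24, adjusted p = 0.0751 by limma). The probe of the Calvin cycle gene SBPASE was listed at 0 in all 6 water samples and in 5 of 6 after MS with sucrose, and whether its annotation fits the spot is open. The light-harvesting gene LHB1B2 (AT2G34420) was at -0.28 (adjusted p = 0.0957 by limma), and passed under median centring at -0.96, at -0.37 without water sample 6 (adjusted p = 0.0226 by limma) and at -0.38 without numbers 5 and 6 of both groups (adjusted p = 0.0369 by limma). The sucrose-phosphate synthase gene ATSPS4F (AT4G10120) was at 0.22 (adjusted p = 0.211 by limma) and at -0.06 under median centring, and passed on the deposited scale at 0.61.

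The 9 lists written after the data were seen repeat some of these genes and are described by their members. Pentatricopeptide repeat proteins, most of which act on RNA in plastids and mitochondria, had 2 members that rose, 7 that fell and 9 that did not pass. The counts that rose and fell were 5 and 1 on the deposited scale and 1 and 3 with adjacent numbers averaged. Under median centring they were 2 and 9 without the 3 members at 0 in 10 or more samples. AT3G13150 rose by 0.70 and AT2G46050 by 0.58, OTP70 (AT4G25270) fell by 0.92 and AT3G26630 by 0.60. The photosynthetic apparatus, 10 genes that include PSBW and PRK, had 3 that rose and 7 that did not pass, against 1 that rose and 5 that fell under median centring without the 2 members at 0 in 10 or more samples. On the deposited scale 2 rose, PRK and AT5G58330, and 0 fell. With adjacent numbers averaged 2 rose, PRK and PSBW, and 0 fell. With a replicate block on the averages 1 rose and 0 fell. Of the 12 genes of photosynthesis assembly and regulation, PIFI (AT3G15840) rose by 0.54, OTP70 and LPA19 (AT1G05385, -1.13) fell, and 9 did not pass. On the deposited scale 4 rose and 0 fell. LPA19 went from 0.218 to 0.150 in mean intensity, and after MS with sucrose it was listed at 0 in sample 5 and at 0.0768, near the offset, in sample 6. In tetrapyrrole and carotenoid synthesis, the geranylgeranyl reductase gene AT1G74470 rose by 0.94, HEMA3 (AT2G31250), for glutamyl-tRNA reductase, fell by 0.63, and 3 did not pass; on the deposited scale 3 rose and 0 fell, and HEMA3 had a mean of 0.524 in both groups. Among 4 amino acid and sulfur assimilation enzymes, AT3G58610, for ketol-acid reductoisomerase, rose by 1.08 and the ATP sulfurylase gene APS4 (AT5G43780) fell by 0.69, though APS4 was at -0.03 on the deposited scale, where 2 of the 4 rose and 0 fell. Of 5 plastid ribosomal protein genes AT5G65220 rose and 4 did not pass, while on the deposited scale and with cyclic loess 2 rose and 0 fell. Of 3 histone H3 genes AT1G13370 rose by 0.81, and all 3 rose on the deposited scale. Of 3 fibrillins AT2G35490 fell by 0.55, with 0.09 on the deposited scale. None of the 4 mTERF family genes passed after quantile normalization, against 4 that rose on the deposited scale, 2 under median centring and 1 with cyclic loess. AT1G79220 was nearest at 0.69 (adjusted p = 0.067 by limma). It passed under the other 3 scalings (adjusted p = 0.00123 to 0.0386), with the number as a replicate block (adjusted p = 0.0327 fixed and 0.0415 random), with zeros missing, without dim probes, and with robust eBayes. It also passed without sample 3 (adjusted p = 0.0277) or sample 4 (adjusted p = 0.0311) of MS with sucrose, or numbers 3 and 4 of both groups. It did not pass with adjacent numbers averaged (adjusted p = 0.265). None of the 9 lists was called by camera, and 1, the pentatricopeptide repeat proteins, had an unadjusted p under 0.05 (p = 0.0398, adjusted p = 0.358, and adjusted p = 0.672 with an estimated correlation).

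Several of these members lost their call under another setting. With adjacent numbers averaged, AT2G46050, PIFI and LPA19 no longer passed, with or without a replicate block, and with a replicate block on the averages PRK, APS4, AT2G35490, AT1G13370, AT3G13150 and HEMA3 did not either. On the deposited scale APS4, OTP70, LPA19, PSBW, HEMA3 and AT2G35490 no longer passed, and under median centring PRK did not. Without numbers 1 and 2 of both groups AT2G46050 and PIFI no longer passed, and without numbers 3 and 4 AT3G13150 and LPA19 did not. AT2G46050 also missed the threshold when any 1 of water samples 1, 3 and 4 or samples 2 and 5 of MS with sucrose was left out, with an adjusted p of 0.0511 to 0.0579 by limma.

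The split into higher and lower depends on the scaling. Quantile normalization gave 48.4% of the calls as higher, cyclic loess 49.7%, the deposited scale 86.5% (1519 higher, 237 lower) and median centring 27.7% (487 higher, 1271 lower). Quantile normalization and cyclic loess match the samples over the range of intensity, which pulls the split towards even. Their near-even split is therefore no evidence of balance. Among all probes, 467 were higher and 227 lower under all 4. This split is no evidence of more rises, since median centring limits the shared rises and the deposited scale limits the shared falls. Quantile normalization shared 622 higher and 230 lower calls with the deposited scale, but 476 higher and 658 lower with median centring. Centring moves a probe with no signal down by the difference of the array medians, and 278 of the 1271 were probes at 0 in 10 or more samples, including all 103 at 0 in all 12. Without such probes, chosen after seeing the data, 487 were higher and 993 lower (32.9% higher). With adjacent numbers averaged, 349 probes were higher and 402 lower, of which 339 and 395 were also called on the 12 samples.

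**Figure D3:**
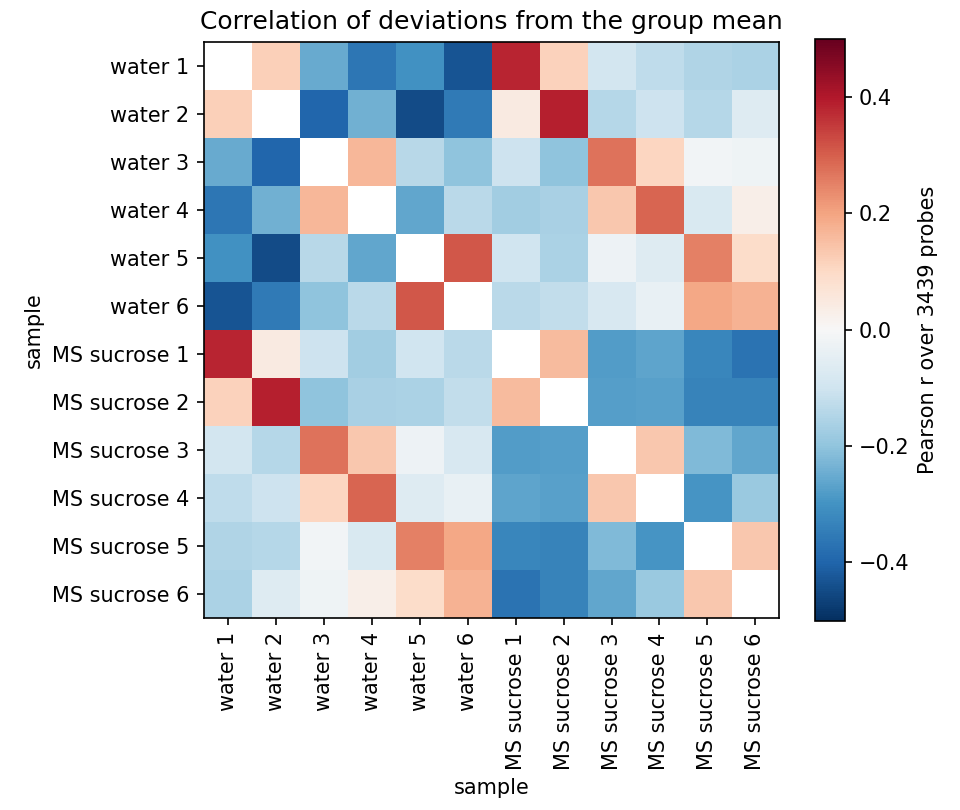
Pearson correlation over all probes between the deviations of 2 samples from their group means, for each pair of the 12 samples; the diagonal is left blank. Same-numbered samples of the groups correlate at 0.174 to 0.390, and adjacent numbers 1 and 2, 3 and 4, 5 and 6 within a group at 0.121 to 0.309.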

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

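The tests of the 2 patterns below were chosen after the values were seen; the comparisons with other splits of the samples were set before they were run. In 7 of 88 sets of 6 samples, 1 sample stood far from the other 5, where chance gives about 4.4. AT1G06730 was lowest in sample 3 of both groups, at a gap of 0.706 of the range in water and 0.695 after MS with sucrose. CYN was highest in water sample 3 (0.637 of the range) and AT5G65220 in water sample 1 (0.633). AT4G31930 was lowest in sample 2 after MS with sucrose, where it was listed at 0 (0.796), and APS4 in water sample 5 (0.649). AT4G37230 was above 0 in water sample 5 only, which makes its gap the whole range (1).

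The call of 1289 probes was matched by 1 of 100 splits of the 12 samples into 6 and 6, the real one, and the highest other split called 1 probe. This would exclude chance for the total if the 12 samples were independent, which the correlations between same and adjacent numbers argue against. The other splits, here and below, also mix the group difference into both sides. Few calls there are what any strong difference between the groups gives, whatever its source. Among the 32 splits that part all 6 same-numbered pairs, 1 reached 1289, again the real one, and the highest other called 1. If adjacent numbers are 1 unit, only 10 splits of the averages exist, which are too few for a share under 0.05; 1 of them, the real one, reached 751 probes and the highest other 0. With 0 lists called by camera, all 100 splits reach that count whatever the data, so for lists the comparison decides nothing; the highest other was 1.

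The log2 ratio of deposited intensities, MS with sucrose over water, lay between 0.85 and 0.97 in the first 6 deciles of brightness and fell from the seventh, the fifth decile exceeding the brightest by 0.86 (SD 0.04 over the 6 same-numbered pairs). A constant added background is excluded, since the intensity difference grew by 0.151 from the first to the sixth decile. Spots at the ceiling do not account for it, since the ninth decile, with no intensity above 5.39, was already 0.51 lower than the fifth. A fall confined to the listed photosynthetic genes is argued against by the 39 other genes of the brightest decile, which were 1.02 lower than the fifth decile (SD 0.07). The brightest decile as a whole was at a log2 ratio of 0.01 and did not fall in deposited intensity. Those 39 genes, however, had a median log2 ratio of -0.15. For the decile as a whole, a fall of abundant transcripts would thus be relative to the dimmer probes. For part of the decile such a fall could be absolute. A fall of abundant transcripts and a non-linear response of the assay that differs between the groups both stay open. The part played by the authors' scaling, which is not given, stays open too.

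Samples with adjacent numbers deviated together within a group, with a mean correlation 0.459 above that of other numbers, so samples 1 and 2, 3 and 4, and 5 and 6 may share a unit. Taking deviations from group means pulls the correlations of other numbers down, within and across the groups, which widens such differences. The correlation of adjacent numbers within a group was estimated at 0.337. Adjacent numbers also correlated across the groups, at 0.0435 to 0.195 against -0.201 to 0.031 for other numbers, a mean difference of 0.215, which argues against duplicate runs of 1 RNA preparation within a group as the whole cause. Across the groups same numbers correlated 0.179 more strongly than adjacent numbers. This does not decide whether adjacent numbers shared plants, since an effect of the number itself would add to that of any shared unit. Shared plants stay open, as do shared arrays or days, which were not tested.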

How the results depend on the processing

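Averaging adjacent numbers, leaving out such pairs and the 9 added lists were chosen after seeing the data. Probes counted as higher in MS_sucrose than water went from 624 to 1519 on the deposited scale, and those counted as lower from 665 to 237, or to 1271 with each array centred on its median. Of these 1271, 278 were at 0 in 10 or more samples and are moved down by the centring itself, as are such members in the list means below; the cause of the rest was not tested. Requiring 2-fold left 175 and 173, averaging adjacent numbers 349 and 402, and the averages with a replicate block 262 and 294. Simulation with errors shared by adjacent numbers within a group, but not across the groups, gave 18.8% false calls on 12 samples. Part of the loss on averaging may be false calls and part lost power, in shares that this simulation does not give. The replicate block on 12 samples gave 638 and 678 and, among named genes, moved only the call of AT1G79220, gained with the block (adjusted p = 0.0327) and absent with adjacent numbers averaged (adjusted p = 0.265). Leaving out 1 sample at a time gave 544 to 619 higher and 589 to 673 lower. The count of gene lists called was 0, and 1 with fry, which does not compare a list with other genes and also called 4 of the added lists; a random block and robust eBayes were not run for lists, and camera kept every list above the threshold under all other settings (lowest adjusted p = 0.101).

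Of the values of 41 named genes under alternatives, 1167 kept direction and side of the threshold, 36 lost the call, 16 gained it and 3 reversed. Those 3 were AT2G35490 on the deposited scale (0.089), and PSBW (-0.53) and ATSPS4F (-0.058) under median centring. The cause was not tested for single genes. Many alternatives, such as leaving out 1 sample, stay close to the main fit, so the tally does not measure robustness. Of the 41 genes, 11 lost the call with a replicate block on the averages. On the deposited scale 5 lost it, 2 gained it and 1 reversed. List means without a call changed sign as follows. On the deposited scale, pentatricopeptide repeat proteins were at 0.18 and photosynthesis assembly at 0.31. Under median centring, amino acid and sulfur enzymes were at -0.036, fibrillins -0.23, the photosynthetic apparatus -0.36, tetrapyrrole and carotenoid synthesis -0.11 and photosystem subunits -0.64. Amino acid and sulfur enzymes were at -0.013 with cyclic loess, -0.020 with zeros missing, -0.036 with array weights and -0.13 without numbers 5 and 6; fibrillins were at -0.016 with cyclic loess and -0.17, and tetrapyrrole and carotenoid synthesis at -0.12, without numbers 1 and 2. Leaving out 1 sample gave -0.038 to 0.039 for amino acid and sulfur enzymes, -0.088 to 0.11 for fibrillins and -0.042 to 0.065 for tetrapyrrole and carotenoid synthesis. Of the 41 genes, 1 had no value with zeros missing and 6 without the 50% dimmest probes. Probes near 0 have no order, and 103 probes were at 0 in all 12 samples.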

Other observations

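Some probes with several genes fall wholly inside 1 of the lists fixed before the data were examined, and no gene is named from them. The 2 such probes of the abscisic acid and osmotic stress list were both lower after MS with sucrose, by -1.20 (adjusted p = 0.00222 by limma) and -1.99 (adjusted p = 0.000171 by limma), and lower under all 4 scalings. With adjacent numbers averaged only the second passed (adjusted p = 0.0198, against 0.0648 for the first, by limma). The probe of the light-harvesting list was at -0.83 (adjusted p = 0.077 by limma) and that of the starch synthesis list at 0.27 (adjusted p = 0.234 by limma), and the latter passed on the deposited scale at 0.94 (adjusted p = 0.00037 by limma). Of all probes, 301 were listed at 0 in all 6 water samples and 138 in all 6 samples after MS with sucrose, while the share of probes at 0 per sample was 14.1% ± 0.615 (SD, n = 6) and 13.2% ± 0.875 (SD, n = 6).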
